A study of Equus asinus with 2 samples.

How the data were processed

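The series holds 2 single-cell RNA libraries of fetal donkey, which the labels give as mesonephric and gonadal tissue at 4 weeks of gestation and ovarian tissue at 8 weeks. Each stage is 1 library, and the labels do not say how many fetuses each holds. The deposited values are whole-number UMI counts per gene and cell barcode, not normalized, which the authors made with Cell Ranger 7.1.0 per the file headers and Cell Ranger 2.1.1 per the submitters' processing notes. The labels describe a DNBelab C series droplet kit, while the barcodes have the form that Cell Ranger writes for the chemistry of 10x Genomics. This discrepancy is open, and so is its effect on how UMIs were counted. The genome build, the gene annotation and whether intronic reads were counted are not given in the sources used here. Every deposited barcode had at least 500 UMIs, and the highest barcode had 124567 UMIs at 4 weeks and 110058 at 8 weeks. UMIs were found for 30503 and 30262 features. Of the features, 16536 carried a gene symbol as deposited and 21981 a locus identifier. A RefSeq gene table of the donkey gave symbols for 768 of the latter, among them CYP17A1, CYP11A1, PLVAP, IGF2, CCL4, MS4A6A, AHSP, GSTM3 and CDH8. No genome was used, so no coordinates are given.

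Barcodes with at least 200 genes were kept, which removed 26 at 4 weeks and 3 at 8 weeks. The limit set beforehand of 20% mitochondrial UMIs removed nothing because 0 features were mitochondrial. Doublets were called in each library by code that follows the Scrublet method, with 2 simulated doublets per cell and an expected rate of 6%. It called 2 and 1 barcodes, 0.0224% and 0.0069%, and in practice removed no doublets. A removal of the top 6% of doublet scores was therefore added as an alternative after seeing the data. The 2 libraries shared 38 barcode sequences.

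Counts were scaled to 10000 per cell, log-transformed and scaled with values limited to 10. The 2000 most variable genes, without haemoglobin genes, gave 30 principal components, a graph of 20 nearest neighbours and Leiden clusters at resolution 1.0 for both libraries together, without batch integration, with seed 1. This gave 33 clusters. Markers of 21 cell classes were fixed before the data were examined, and the rule that turns them into names was set after the clusters were first seen. A marker counted when it stood at least 2-fold over all other cells with 10 CPM added. A class needed at least 3 markers, at least 33.3% of its markers and a lead of 10 percentage points, and clusters whose 10 leading genes belonged to another class stayed unnamed. Clusters with very low UMIs or high doublet scores also stayed unnamed.

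Clusters with over 3 times the median UMIs were treated in 3 ways in turn, each set after the effect of the one before was seen. At first there was no rule. Then such a cluster was left unnamed if any second class also reached 33.3% of its markers. Last, it was left unnamed only if that second class is itself named in the same cells. The last rule keeps cluster 22 (137 and 200 cells, median 43187 and 34897 UMIs, led by POU5F1, NANOG and TFAP2C) out of the germ cells. Both rules gave 520 and 1074 germ-cell-like cells, and no rule gave 657 and 1274. With each library clustered alone, the 8-week Sertoli-like share was 7.58% under the last rule, which is used here, and with no rule, but 0.864% under the earlier rule.

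Levels are UMIs of a gene summed over the cells of a class, as CPM, that is per 1000000 UMIs, with exact Poisson intervals at 95%. Ratios of 8 over 4 weeks carry exact conditional binomial intervals, and shares of cells carry Clopper-Pearson intervals. A count of 0 was given the limit that 3 counts would set, in place of the interval's upper end. All of these cover counting error only and leave out the spread between animals, so no test and no p-value is reported and cells were not used as replicates. Classes were compared if each library gave at least 50 cells (20 for germ cells), which left 8 classes. Of 24 gene lists fixed before the data were examined, 22 were compared. For each list the median log2 ratio was taken over members with at least 10 UMIs, with 0.5 UMI added to each sum. It carries a 95% interval from the order statistics of its members and a percentile among 10000 random lists of the same size, matched in 20 bins of expression. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with shallower cells left out. Endothelial-like cells served as the class that should lack germ cell, Sertoli and steroidogenic genes, and show the level of free RNA. Macrophage-like cells should lack these genes too. At 8 weeks they held AMH, NR0B1, POU5F1, CYP17A1 and INSL3 at higher levels than endothelial-like cells, so the endothelial-like level can understate free RNA.

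The named genes follow a rule fixed before the data were examined. The first part takes up to 12 genes with the highest and 12 with the lowest ratio per class. They needed at least 100 CPM in the higher library, an interval wholly beyond 2-fold and a level in the class at least that over all cells. Locus identifiers, ribosomal protein, mitochondrial and haemoglobin genes were left out. The second part takes the 2 highest and 2 lowest members of each list with at least 20 CPM, and the third takes up to 4 markers of each class by level. The text names part of the genes that the rule gives, and says where a gene was chosen after its values were seen.

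The gene ratios, intervals, size rule and list percentiles were tested on simulated counts made from the germ cell profile of 18866 genes, of which 200 were changed. The counts were drawn with Poisson error around class sums, which is the error that the intervals assume. Clustering, naming, free RNA and the spread between cells were not simulated. Of 100 genes changed 2-fold, 94 had intervals that held the true ratio and 14 met the size rule, and of 100 genes changed 4-fold the numbers were 95 and 100. Of 1821 unchanged genes with at least 100 CPM, 1738 had intervals that held the true ratio and 0 met the size rule. Among 100 unchanged lists of 25 genes, 1 lay outside the middle 95% of random lists.

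Alternatives chosen before the data were examined were at least 1000 genes per cell, no doublets removed, resolutions 0.5 and 2.0, each library clustered alone, thinned cells, totals without ribosomal protein and haemoglobin genes, members with at least 50 UMIs and every cell given the same weight. Those added after seeing the data were the removal of the top doublet scores, naming without the rule on high UMIs, and only clusters with at least 50 cells of each library. Of the 11 genes of the sex check fixed in advance, only SRY was found among the features by symbol, and the other genes are not analysed here. The software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.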

Results

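Single-cell RNA sequencing was compared between 2 libraries of fetal donkey (Equus asinus) tissue: gonad with mesonephros at 4 weeks of gestation, and tissue labelled ovary at 8 weeks. The mesonephros is the transient embryonic kidney that lies beside the forming gonad. The 4-week library held 8938 cell barcodes with 122341903 UMIs (unique molecular identifiers, each standing for a captured RNA molecule), a median of 7728 UMIs and 3141.5 genes per barcode. The 8-week library held 14593 barcodes with 155128130 UMIs, a median of 5877 UMIs and 2635 genes. After filtering, 8910 and 14589 cells were kept. Each group was 1 library, so no test of a difference between the stages was possible. The intervals given are 95% intervals of counting error and hold no spread between animals. Stage, dissected tissue and library also differed together and cannot be told apart. Clusters of cells were named from marker genes fixed before the data were examined, and the names carry "-like" because no other evidence of identity was used. Levels are CPM, the UMIs of a gene per 1000000 UMIs summed over the cells of a class, given as the 4-week value and then the 8-week value.

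Both libraries held germ cells, gonadal somatic cells, vessels and blood, and the 4-week library held mesonephric kidney cells that the library labelled ovary nearly lacked. Stroma-like cells made up 15.7% (15.0 to 16.5) of the 4-week cells and 39.962% (39.2 to 40.8) of the 8-week cells. Macrophage-like cells took 1.58% (1.33 to 1.86) and 6.07% (5.69 to 6.47), and endothelial-like cells 17.0% (16.3 to 17.8) and 4.28% (3.96 to 4.62). Sertoli-like cells, the supporting cells of the testis cord, took 7.44% (6.91 to 8.01) and 6.37% (5.98 to 6.78). Germ-cell-like cells took 5.84% (5.36 to 6.34) and 7.36% (6.94 to 7.80), which were 520 and 1074 cells. No cluster was named for pre-granulosa cells, the supporting cells of the fetal ovary, in either library. This does not show that such cells were absent. Unnamed clusters such as 6 (36 and 971 cells) and 12 (79 and 603 cells) are not described here.

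Steroidogenic-like cells, which carried the androgen enzymes of Leydig or theca cells, took 2.01% (1.73 to 2.32) and 3.83% (3.52 to 4.15). Smooth-muscle-like cells took 1.38% (1.15 to 1.65) and 2.73% (2.47 to 3.01). Erythroid-like cells took 5.61% (5.14 to 6.11) and 0.425% (0.326 to 0.544), and lymphoid-like cells 1.28% (1.06 to 1.54) and 0.322% (0.237 to 0.428). Mesonephric-tubule-like cells took 10.2% (9.55 to 10.8) of the 4-week library, with the endocytic receptor LRP2 at 328 CPM, the cadherin CDH6 at 463 CPM and the renal transcription factor PAX8 at 262 CPM. Cells like distal tubule or duct took 4.09% (3.68 to 4.52), with the salt transporters SLC12A3 and SLC12A1 at 1205 and 597 CPM and WFDC2 at 635 CPM. Podocyte-like cells took 1.16% (0.945 to 1.40), with the slit-diaphragm gene NPHS1 at 1230 CPM and PTPRO at 3069 CPM. Of the 14589 cells of the library labelled ovary, 1 was distal-tubule-like and 0 were tubule-like or podocyte-like, which allows a share of up to 0.0206%. Unnamed clusters held 26.7% and 28.7% of the cells.

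Some of these shares moved with the clustering by more than 1.5 times. The stroma-like share was 20.6% and 60.5% at the lower resolution, 2.5% and 17.9% at the higher resolution, and 16.1% and 0% with each library clustered alone, which left no 8-week cluster named stroma. The erythroid-like shares were 3.0% and 0.166% with at least 1000 genes per cell. The 8-week smooth-muscle-like share was 5.12% at the lower resolution and 5.98% with each library clustered alone, which also put the lymphoid-like shares at 0% and 0.631%, the other way round. At 4 weeks the podocyte-like share was 7.83% with no doublets removed, which changed the clusters although it added only 3 cells, and 2.31% at the higher resolution. The Sertoli-like shares moved by less but also turned round, to 6.14% and 7.58% with each library clustered alone. The unnamed shares turned round at the lower resolution (28.6% and 3.06%), with no doublets removed (16.9% and 13.8%) and with the highest doublet scores removed (26.4% and 22.6%). They rose to 40.3% and 52.5% at the higher resolution and to 31.3% and 63.3% with each library clustered alone. In both of these settings most 8-week cells were unnamed. The distal-tubule-like share was 2.48% with at least 1000 genes and 7.09% at the lower resolution. At the lower resolution no cluster was named mesonephric tubule, podocyte or lymphoid: 1437 cells of the 4-week library met 63.6% of the podocyte and 57.9% of the tubule markers in 1 cluster, which stayed unnamed.

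**Figure D1:**
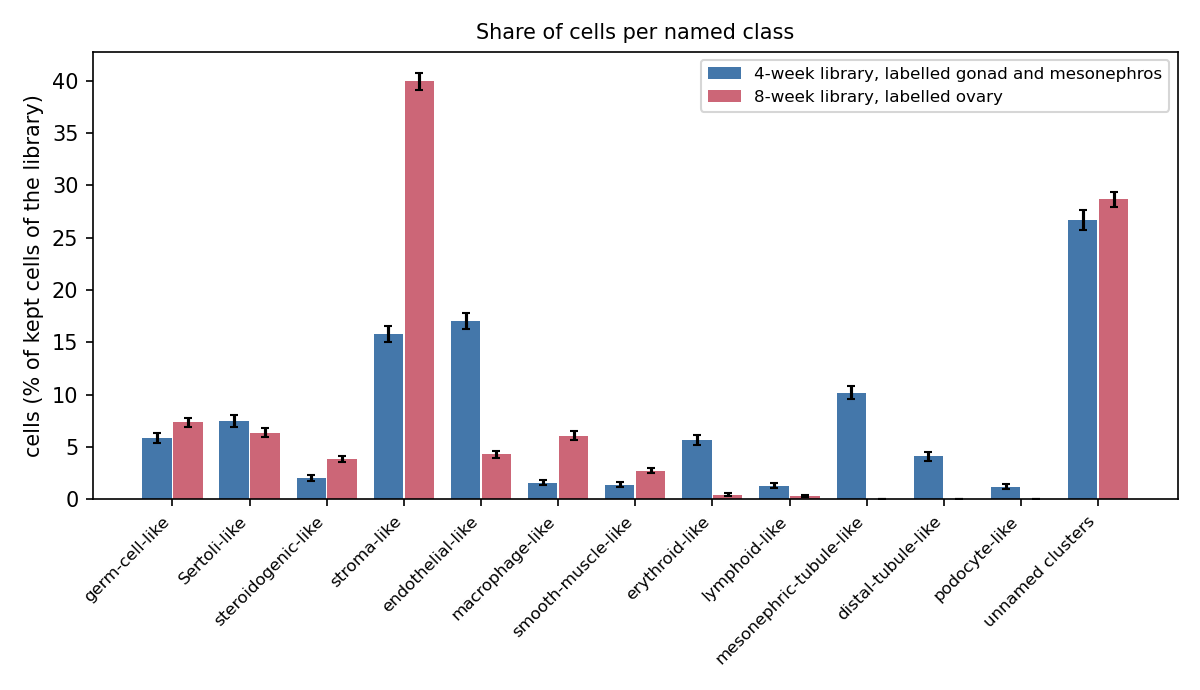
Share of kept cells in each named class (vertical axis in percent, bars for the 4-week library and the 8-week library labelled ovary, black lines for exact 95% Clopper-Pearson intervals of counting error). Stroma-like cells took 15.7% and 40.0% of the cells, and mesonephric-tubule-like cells 10.2% and 0%.

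Supporting cells in both libraries, including the library labelled ovary, carried the genes of Sertoli cells. AMH, the hormone that makes the Müllerian ducts regress, stood at 2958 CPM (2928 to 2989) in Sertoli-like cells at 4 weeks and at 3436 CPM (3408 to 3465) at 8 weeks. SOX9, the transcription factor that drives Sertoli fate, stood at 556 and 247 CPM, 2.25-fold lower, 2.16 to 2.34. HSD17B3, which makes testosterone from androstenedione, stood at 203 and 153 CPM and the prostaglandin D synthase PTGDS at 146 and 124 CPM. AMH, SOX9, HSD17B3, PTGDS and DHH, given below, belong to the markers that named the class. Their levels are therefore no separate evidence of its identity. The Sertoli-like cells came from cluster 17 (478 and 41 cells) and cluster 4 (185 and 888 cells), so the class was made of different clusters at the 2 stages. Median depth was 13843 and 12609 UMIs per Sertoli-like cell, against 7556 and 5506 in endothelial-like cells, a class that should lack AMH.

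With each cell thinned to 1000 UMIs, 88.4% (85.7 to 90.8) of the 4-week and 89.4% (87.2 to 91.3) of the 8-week Sertoli-like cells held an AMH UMI, against 2.71% (1.94 to 3.67) and 6.53% (4.62 to 8.93) of the endothelial-like cells. Thinning left out 17 and 34 Sertoli-like cells and 41 and 73 endothelial-like cells. Without thinning the shares were 98.0% and 98.5% of the Sertoli-like cells and 19.2% and 32.5% of the endothelial-like cells. Several other genes of the sex-determination pathways were chosen after their values were seen. SRY, the Y-linked gene that starts testis formation, stood at 11.0 CPM (9.27 to 13.0) and 9.39 CPM (7.97 to 11.0) in Sertoli-like cells. Over all kept cells of the 8-week library SRY had 1494 of 155103162 UMIs. Its 8-week level in Sertoli-like cells was therefore not above that of the library as a whole. After thinning, a SRY UMI was found in 0.464% (0.0960 to 1.35) and 1.12% (0.537 to 2.05) of the Sertoli-like cells and in 0.0680% (0.00200 to 0.377) and 0.363% (0.0440 to 1.31) of the endothelial-like cells, so that the shares of the classes overlapped at this depth. Without thinning they were 16.4% and 14.9% against 0.527% and 2.24%. DHH, the Hedgehog ligand of Sertoli cells, stood at 61.1 and 55.9 CPM and DMRT1, which keeps male fate, at 75.6 and 54.8 CPM. FOXL2, the transcription factor of granulosa cells, stood at 0.317 and 0.732 CPM and RSPO1, a WNT activator of the ovary, at 0.238 and 0.549 CPM. WNT4 stood at 0.872 and 2.38 CPM, a log2 ratio of 1.40 that turned to −0.67 at the higher resolution, and the WNT receptor LGR5 at 30.4 and 29.6 CPM.

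**Figure D2:**
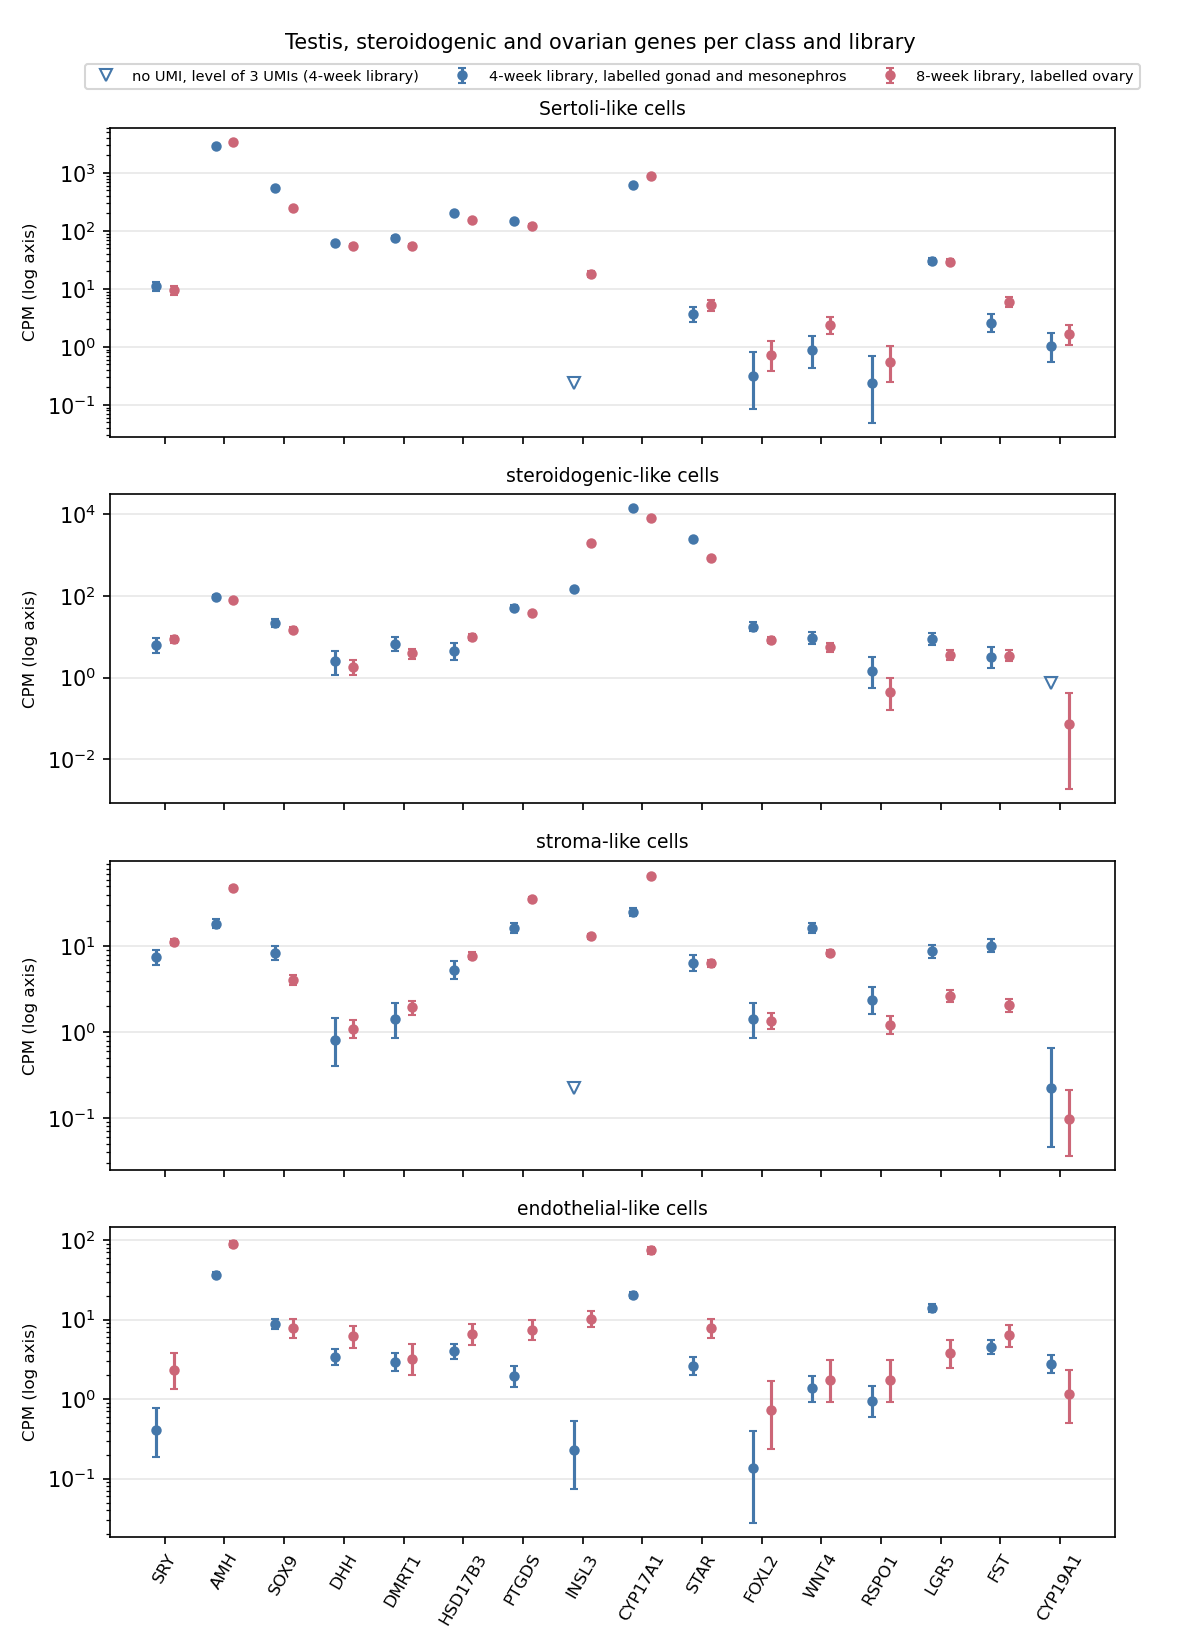
Levels of 16 genes of testis, steroid and ovary pathways (horizontal axis) in 4 classes of cells (panels), in CPM on a log axis, with exact 95% Poisson intervals of counting error and open triangles at the level of 3 UMIs where the 4-week library had no UMI. In Sertoli-like cells AMH stood at 2958 and 3436 CPM and FOXL2 at 0.317 and 0.732 CPM in the 4-week library and the library labelled ovary.

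The testis list as a whole shifted little in Sertoli-like cells. Its median log2 ratio of 8 over 4 weeks was −0.20 (−0.46 to 0.22, percentile 26.4), where the interval is over the members and the percentile is among 10000 random lists of like expression, a description and not a p-value. Of 18 measured members, 6 were higher and 12 lower, with NR0B1, a repressor of steroid genes, at 35.4 and 121 CPM, 3.42-fold higher, 3.08 to 3.79, and MRO at 24.3 and 4.94 CPM, 4.93-fold lower, 3.85 to 6.37. The ovarian list had a median of −0.29 (−0.93 to 0.42, percentile 13.3), with 15 of 24 members lower, among them the Notch target HES1 (495 and 131 CPM, 3.77-fold lower, 3.59 to 3.96) and RUNX1 (118 and 42.2 CPM, 2.81-fold lower, 2.57 to 3.08). Early gonad transcription factors had a median of 0.28 (−0.78 to 1.77, percentile 91.6), which turned to −0.55 at the higher resolution. LHX9 stood at 4.68 and 31.0 CPM and TCF21 at 2.06 and 20.007 CPM, while WT1, a Sertoli and podocyte regulator, stood at 240 and 124 CPM. Retinoic acid genes had a median of 0.082 (−0.47 to 1.43, percentile 71.8) over 16 members. The retinoid-binding protein CRABP2 stood at 7.69 and 84.6 CPM and the synthesis enzyme ALDH1A2 at 17.5 and 72.4 CPM, a log2 ratio of 2.04 that was −0.034 in cluster 4 alone. At 8 weeks endothelial-like cells held NR0B1 at 91.0, LHX9 at 20.5, TCF21 at 14.4, CRABP2 at 51.8 and ALDH1A2 at 59.9 CPM, so the higher levels of these genes in Sertoli-like cells lie little above background.

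WNT genes had a median of 0.55 (−0.25 to 1.50, percentile 99.97) in Sertoli-like cells, with 17 of 28 members higher, among them the WNT inhibitor SFRP1 (8.72 and 49.5 CPM, 5.68-fold higher, 4.65 to 6.99), while ZNRF3 stood at 120 and 60.3 CPM. The WNT list also stood at 0.47 in endothelial-like cells, which held SFRP1 at 41.7 CPM at 8 weeks, near the level in Sertoli-like cells. BMP and TGF-beta genes had a median of 0.23 (−0.40 to 0.70, percentile 95.4) over 27 members, and the BMP target ID3 stood at 173 and 474 CPM, 2.74-fold higher, 2.62 to 2.88. Cell-cycle genes leaned higher at 8 weeks over the class as a whole. The S phase list had a median of 0.33 (0.034 to 0.54, percentile 99.8) with 21 of 29 members higher, such as the thymidylate synthase TYMS (83.7 and 158 CPM). The G2 and M phase list had a median of 0.34 (−0.078 to 0.60, percentile 99.8) with 20 of 33 higher, such as CDK1 (19.4 and 57.2 CPM). Within cluster 4, the 1 Sertoli-like cluster with at least 50 cells of each library, the S phase median turned to −0.21 and the G2 and M phase median to −0.87, an alternative chosen after seeing the data.

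Among single genes, Sertoli-like cells at 8 weeks had higher levels of the secreted phosphoprotein SPP1 (985 and 2749 CPM, 2.79-fold higher, 2.74 to 2.85), and the calcium-binding S100A11 (443 and 1321 CPM, 2.98-fold higher, 2.90 to 3.07). The same held for the ubiquitin gene UBB (1366 and 3821 CPM, 2.80-fold higher, 2.75 to 2.84), the glycolytic enzyme GAPDH (1403 and 3670 CPM, 2.62-fold higher, 2.57 to 2.66) and the mitotic ubiquitin enzyme UBE2C (82.5 and 255 CPM, 3.09-fold higher, 2.89 to 3.31). They had lower levels of the zinc-finger gene ZNF398 (289 and 34.3 CPM, 8.43-fold lower, 7.71 to 9.23), the hypoxia-responsive NDRG1 (128 and 16.8 CPM, 7.61-fold lower, 6.70 to 8.68) and the phosphodiesterase PDE4B (165 and 24.1 CPM, 6.86-fold lower, 6.16 to 7.66). Lower too were the surface protein CD83 (421 and 80.9 CPM, 5.21-fold lower, 4.90 to 5.54), the lipid phosphatase LPIN1 (213 and 44.3 CPM, 4.79-fold lower, 4.41 to 5.21) and the repressor ETV6 (294 and 64.6 CPM, 4.55-fold lower, 4.25 to 4.88). Most of these gaps shrank within cluster 4. There the log2 ratio of ZNF398 was −0.76 in place of −3.08 and that of NDRG1 −1.69 in place of −2.93. PDE4B stood at −0.58 in place of −2.78 and CD83 at −0.91 in place of −2.38. LPIN1 stood at −0.45 in place of −2.26, ETV6 at −0.68 in place of −2.19 and UBE2C at 0.46 in place of 1.63.

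Steroidogenic-like cells, all from cluster 11 in both libraries, showed more INSL3 and less of most steroid enzymes in the library labelled ovary. INSL3, the Leydig cell hormone of testis descent, stood at 144 and 1925 CPM, 13.4-fold higher, 12.3 to 14.5. CYP17A1, the enzyme that makes androgen precursors, stood at 13594 and 7922 CPM, 1.72-fold lower, 1.70 to 1.73, and STAR, which carries cholesterol into the mitochondrion, at 2376 and 839 CPM, 2.83-fold lower, 2.76 to 2.91. CYP11A1, which cleaves the cholesterol side chain, stood at 2712 and 1711 CPM, 1.59-fold lower, 1.55 to 1.62 and its electron donor FDX1 at 3273 and 2087 CPM, 1.57-fold lower, 1.54 to 1.60. The steroidogenesis list, which includes INSL3, had a median log2 ratio of −0.66 (−1.26 to −0.078, percentile 0), with 15 of 19 members lower, 7 of them at least 2-fold. POR, the reductase that serves these enzymes, stood at 405 and 136 CPM, 2.98-fold lower, 2.79 to 3.19 and CYB5A, a cofactor of CYP17A1, at 228 and 254 CPM, 1.11-fold higher, 1.03 to 1.20.

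With each cell thinned to 1000 UMIs, an INSL3 UMI was found in 7.96% (4.42 to 13.0) of the 4-week and 49.1% (44.8 to 53.4) of the 8-week steroidogenic-like cells, against 0.0680% (0.00200 to 0.377) and 0.726% (0.198 to 1.85) of the endothelial-like cells. Thinning left out 3 and 12 steroidogenic-like cells, whose class had median depths of 22320 and 19933.5 UMIs against 7556 and 5506 in endothelial-like cells. Without thinning the shares were 24.6% and 83.3% against 0.329% and 6.41%.

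The matrix, cell-cycle and Hedgehog lists went the other way in the same cells. The matrix list, made of genes typical of stroma, had a median of 1.18 (0.70 to 1.73, percentile 100), with 32 of 40 members higher, 21 of them at least 2-fold. Whether RNA of stroma cells lies behind this was not tested in this class, so a share of such RNA may also enter the other ratios of this class. The S phase list had a median of 0.84 (0.47 to 0.91, percentile 100) with 26 of 29 members higher, such as the replication helicase gene MCM2 (9.42 and 31.9 CPM, 3.39-fold higher, 2.43 to 4.85), while GMNN, an inhibitor of replication licensing, stood at 142 and 87.3 CPM. The G2 and M phase list had a median of 0.96 (0.64 to 1.09, percentile 100) with 29 of 33 higher, 15 of them at least 2-fold, such as CDK1 (7.69 and 39.2 CPM, 5.10-fold higher, 3.55 to 7.58) and UBE2C (30.003 and 140 CPM, 4.68-fold higher, 3.89 to 5.67), while AURKA stood at 42.2 and 37.6 CPM. With the highest doublet scores removed, an alternative chosen after seeing the data, the G2 and M phase median was 2.02. Hedgehog genes had a median of 0.94 (0.10 to 2.22, percentile 99.99) with 10 of 11 higher, and 1.52 with the highest doublet scores removed. The Hedgehog receptor and target PTCH1 stood at 28 and 117 CPM, 4.17-fold higher, 3.44 to 5.09, below the 242 CPM of stroma-like cells at 8 weeks. The Hedgehog list was also higher in Sertoli-like (0.98), germ-cell-like (1.24), endothelial-like (0.86) and macrophage-like cells (1.53). Ribosomal protein genes had a median of 0.31 (0.11 to 0.44, percentile 99.6) with 34 of 44 higher, where RPS12 stood at 2355 and 4363 CPM and RPS27 at 3690 and 1947 CPM.

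Other genes higher in these cells at 8 weeks were OLFML3 (41.4 and 260 CPM, 6.28-fold higher, 5.38 to 7.38), AEBP1 (22.3 and 106 CPM, 4.75-fold higher, 3.84 to 5.95) and the glutathione transferase gene GSTM3 (1412 and 3012 CPM, 2.13-fold higher, 2.08 to 2.19). Stroma-like cells held OLFML3 at 209 and AEBP1 at 57.9 CPM at 8 weeks. Lower were the cadherin CDH18 (137 and 25.9 CPM, 5.29-fold lower, 4.62 to 6.06) and the kinase anchor AKAP12 (648 and 172 CPM, 3.77-fold lower, 3.57 to 3.99). The sterol carrier STARD4 (111 and 32.9 CPM, 3.36-fold lower, 2.94 to 3.84), the acetate ligase ACSS2 (420 and 126 CPM, 3.33-fold lower, 3.11 to 3.56) and the citrate lyase ACLY (1307 and 412 CPM, 3.17-fold lower, 3.06 to 3.30) were lower too.

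Germ-cell-like cells had lower levels of most pluripotency genes and higher levels of genes of later germ cells in the library labelled ovary. POU5F1, a pluripotency factor kept by primordial germ cells, stood at 927 and 427 CPM, 2.17-fold lower, 2.09 to 2.25 and TFAP2C, a regulator of primordial germ cell fate, at 358 and 187 CPM, 1.92-fold lower, 1.81 to 2.03. NANOG stood at 357 and 286 CPM, 1.25-fold lower, 1.19 to 1.32 and the receptor gene KIT at 337 and 270 CPM, 1.25-fold lower, 1.18 to 1.32. DAZL, an RNA-binding protein that licenses germ cells for sexual differentiation, stood at 39.4 and 128 CPM, 3.25-fold higher, 2.86 to 3.70. The cells came from clusters 7 (353 and 611 cells) and 13 (167 and 463 cells) in both libraries.

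The pluripotency and primordial germ cell list had a median log2 ratio of −0.49 (−1.01 to 0.14, percentile 0.690), with 16 of 22 measured members lower and 6 higher. The RNA-binding repressor LIN28A stood at 57.4 and 15.1 CPM, 3.80-fold lower, 3.18 to 4.55 and PRDM14 at 33.8 and 15.1 CPM, 2.23-fold lower, 1.83 to 2.72. DND1, which protects germ cell messages, stood at 70.0 and 122 CPM, 1.74-fold higher, 1.57 to 1.93 and NANOS3 at 146 and 181 CPM. The differentiation list had a median of 0.94 (0.50 to 1.62, percentile 100), with 22 of 25 members higher, 12 of them at least 2-fold. Among them were MAEL, a piRNA pathway gene (31.2 and 110 CPM, 3.52-fold higher, 3.05 to 4.07), and SOHLH1 (4.24 and 23.9 CPM, 5.65-fold higher, 3.89 to 8.47), while TEX14 stood at 57.4 and 39.8 CPM. TDRD9 stood at 60.6 and 51.1 CPM, a log2 ratio of −0.25 that turned to 0.062 with every cell given the same weight. The differentiation list was also higher in some of the classes that should lack it, with medians of 1.24 (−0.15 to 2.51, percentile 100) in Sertoli-like, 1.13 (0.081 to 1.97, percentile 99.97) in endothelial-like and 1.75 (−0.15 to 2.52, percentile 94.6) in macrophage-like cells, so the direction was not particular to germ-cell-like cells. Levels there were low, with DAZL at 0.555 and 5.49 CPM in Sertoli-like and 0.273 and 2.49 CPM in endothelial-like cells. Some lists of somatic genes leaned higher in germ-cell-like cells too, with intervals that include 0. Medians were 0.77 (−0.21 to 1.77, percentile 99.84) for early gonad transcription factors, 0.67 (−0.19 to 1.64, percentile 99.57) for the testis list and 0.51 (−0.012 to 0.86, percentile 99.2) for steroidogenesis. The ovarian list leaned the other way, at −0.34 (−0.93 to 0.26, percentile 5.49).

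With each cell thinned to 1000 UMIs, a POU5F1 UMI was found in 60.7% (56.2 to 65.0) and 32.8% (29.9 to 35.9) of the germ-cell-like cells, against 0.745% (0.372 to 1.33) and 0.726% (0.198 to 1.85) of the endothelial-like cells. A DAZL UMI was found in 3.19% (1.84 to 5.14) and 12% (10.1 to 14.2) of the germ-cell-like cells and in 0% of the endothelial-like cells of both libraries, where counts of 0 allow up to 0.203% and 0.544%. Thinning left out 19 and 93 germ-cell-like cells. Median depths were 11344.5 and 7147 UMIs in germ-cell-like and 7556 and 5506 in endothelial-like cells. Without thinning, POU5F1 was found in 92.9% and 66.4% of the germ-cell-like cells against 6.26% and 5.61%, and DAZL in 28.7% and 51.2% against 0.329% and 1.60%.

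**Figure D3:**
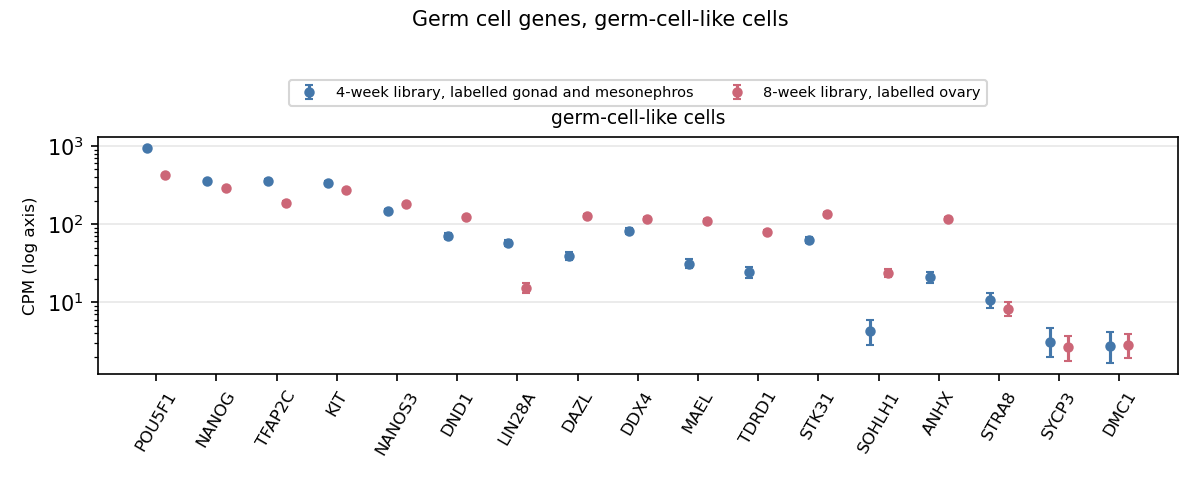
Levels of 17 germ cell genes in germ-cell-like cells of the 4-week library and the 8-week library labelled ovary, in CPM on a log axis, with exact 95% Poisson intervals of counting error. POU5F1 stood at 927 and 427 CPM, DAZL at 39.4 and 128 CPM and STRA8 at 10.7 and 8.20 CPM.

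The meiosis list leaned higher at 8 weeks, with a median of 0.50 (−0.046 to 1.07, percentile 99.5), whose interval includes 0, and 19 of 29 members higher. Classes that should lack these genes gave 0.43 (−0.034 to 1.05, percentile 96.6) in steroidogenic-like, 0.50 (−0.13 to 1.59, percentile 75.3) in macrophage-like and −0.36 (−1.07 to 0.20, percentile 5.62) in endothelial-like cells, so the direction was not particular to germ-cell-like cells. ANHX stood at 21 and 116 CPM, 5.51-fold higher, 4.66 to 6.55 and SYCE2, a central element of the synaptonemal complex, at 7.79 and 23.9 CPM, 3.07-fold higher, 2.30 to 4.16, while MEI4 stood at 171 and 87.2 CPM, 1.97-fold lower, 1.81 to 2.14 and SYCP1 at 22.7 and 16.2 CPM. STRA8, which starts meiosis under retinoic acid, and SYCP3, of the synaptonemal complex, were chosen after their values were seen. They stood at 10.7 and 8.20 CPM, ratio 0.769, 0.565 to 1.05, and 3.14 and 2.65 CPM, ratio 0.843, 0.476 to 1.51. After thinning, a STRA8 UMI was found in 0.599% (0.124 to 1.74) and 1.43% (0.782 to 2.38) of the germ-cell-like cells against 0.406% (0.149 to 0.882) and 0% (up to 0.544) of the endothelial-like cells. A SYCP3 UMI was found in 0.200% (0.00500 to 1.11) and 0.204% (0.0250 to 0.735) against 0.271% (0.0740 to 0.692) and 0% (up to 0.544), so that SYCP3 lay at background. Unthinned, STRA8 was found in 11.9% and 7.73% of the germ-cell-like cells against 4.08% and 1.60%, and SYCP3 in 3.65% and 2.70% against 2.37% and 1.12%.

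DNA methylation genes had a median of −0.17 (−0.84 to 0.11, percentile 25.5) in germ-cell-like cells, with 8 of 13 members lower, among them the demethylating oxygenase TET1 (288 and 130 CPM, 2.21-fold lower, 2.07 to 2.37) and the repressor TRIM28 (607 and 338 CPM, 1.80-fold lower, 1.72 to 1.87). The S phase list had a median of −0.13 (−0.36 to 0.12, percentile 34.2) over 29 members, where the chromatin remodeller HELLS stood at 1289 and 513 CPM and SLBP at 45.2 and 108 CPM. The G2 and M phase list had a median of −0.30 (−0.53 to −0.12, percentile 3.65) with 26 of 33 lower, where CENPF stood at 925 and 451 CPM and CKS2 at 351 and 615 CPM. Genes that mark early embryonic timing had a median of −0.61 (−1.16 to −0.024, percentile 0.0900) with 13 of 17 lower, LIN28A among them. Stress genes had a median of 0.39 (0.043 to 0.54, percentile 98.3), which was −0.0026 when a cluster of high-UMI cells was also named germ cell.

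Genes higher in germ-cell-like cells at 8 weeks also included TEX30 (39.5 and 156 CPM, 3.95-fold higher, 3.48 to 4.48) and the replication protein genes RPA3 (130 and 445 CPM, 3.41-fold higher, 3.19 to 3.66) and RPA2 (80.5 and 254 CPM, 3.15-fold higher, 2.88 to 3.45). ID3 (114 and 386 CPM, 3.38-fold higher, 3.14 to 3.64) and FMR1NB (189 and 602 CPM, 3.18-fold higher, 3.01 to 3.38) were higher too. Lower were SHISA9 (105 and 19.6 CPM, 5.39-fold lower, 4.64 to 6.27), the synaptic adhesion gene LRRTM4 (162 and 31.4 CPM, 5.16-fold lower, 4.58 to 5.81) and NALF1 (538 and 106 CPM, 5.06-fold lower, 4.75 to 5.40), as were the cadherin CDH8 (224 and 45 CPM, 4.97-fold lower, 4.51 to 5.50) and the receptor TNFRSF19 (185 and 41.0 CPM, 4.52-fold lower, 4.07 to 5.02). With every cell given the same weight the log2 ratio of SHISA9 was −1.77 in place of −2.43 and that of NALF1 −1.68 in place of −2.34.

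Stroma-like cells of the library labelled ovary had lower HOX genes, lower Notch and BMP genes and more of the matrix proteoglycans decorin and lumican. The HOX list, which sets position along the body axis, had a median log2 ratio of −1.33 (−2.63 to −0.42, percentile 0), with 29 of 32 members lower, 18 of them at least 2-fold. It was −3.04 at the higher resolution, −0.67 with thinned cells and −0.63 over members with at least 50 UMIs. HOXB2 stood at 7.74 and 22.0 CPM, 2.85-fold higher, 2.33 to 3.51. The cells came from other clusters at each stage: cluster 5 gave 953 cells at 4 weeks and 70 at 8 weeks, cluster 0 gave 76 and 2387, cluster 3 gave 27 and 1783 and cluster 2 gave 347 and 1590.

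The matrix list had a median of −0.16 (−0.51 to −0.073, percentile 21.2) in stroma-like cells with 29 of 41 members lower, and −0.65 at the higher resolution. DCN (decorin) stood at 1276 and 2103 CPM, 1.65-fold higher, 1.62 to 1.67 and LUM (lumican), named after its values were seen, at 82.2 and 161 CPM, 1.96-fold higher, 1.84 to 2.09. POSTN (periostin) stood at 128 and 20.5 CPM, 6.24-fold lower, 5.80 to 6.72 and COL14A1 at 38.4 and 8.36 CPM, 4.59-fold lower, 4.06 to 5.20. COL1A1 stood at 1377 and 1378 CPM, and COL1A2 at 1851 and 1818 CPM, a log2 ratio of −0.026 that turned to 0.016 when ribosomal protein and haemoglobin genes were left out of the total. DLK1 stood at 841 and 1700 CPM, 2.02-fold higher, 1.98 to 2.06. Notch genes had a median of −0.59 (−1.26 to −0.056, percentile 2.46) with 13 of 17 lower, and −1.32 at the higher resolution. Their target HES1 stood at 132 and 27.1 CPM, 4.87-fold lower, 4.55 to 5.21 and the ligand JAG1 at 23.5 and 9.83 CPM, 2.39-fold lower, 2.08 to 2.75. BMP and TGF-beta genes had a median of −0.33 (−0.74 to −0.036, percentile 2.42) with 22 of 27 lower, and −1.05 at the higher resolution. The receptor BMPR1B stood at 48.1 and 6.94 CPM, 6.93-fold lower, 6.12 to 7.85.

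The ovarian list had a median of −0.98 (−1.69 to −0.36, percentile 0) in stroma-like cells, with 21 of 23 members lower, among them the WNT effector LEF1 (27.8 and 5.13 CPM, 5.41-fold lower, 4.65 to 6.31). The testis list had a median of 0.54 (−0.66 to 1.13, percentile 99.8), which turned to −0.15 at the higher resolution, and stood at 0.73 in endothelial-like cells. AMH in stroma-like cells (48.1 CPM at 8 weeks) lay below its level in endothelial-like cells (88.8 CPM), at background. Early gonad transcription factors had a median of −0.29 (−1.33 to 0.047, percentile 13.1) with GATA6 at 55.5 and 20.1 CPM and GATA4 at 106 and 131 CPM. Genes of early embryonic timing had a median of −0.57 (−0.67 to −0.020, percentile 0.140) with 13 of 17 lower, such as IGF2BP1 (112 and 41.5 CPM, 2.71-fold lower, 2.54 to 2.89). Stress genes had a median of −0.50 (−0.79 to −0.066, percentile 0.0600) with 16 of 21 lower, such as ATF3 (110 and 40.5 CPM, 2.72-fold lower, 2.55 to 2.90). Thinning and the higher resolution moved the median of all genes in this class by 0.12 and 0.11.

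Single genes of stroma-like cells with higher levels at 8 weeks were the transcription factor MSC (12.8 and 129 CPM, 10.1-fold higher, 8.65 to 11.8), NR0B1 (209 and 513 CPM, 2.45-fold higher, 2.36 to 2.55), the matrilin MATN2 (56.2 and 154 CPM, 2.74-fold higher, 2.54 to 2.95) and the integrin ITGA4 (167 and 405 CPM, 2.43-fold higher, 2.32 to 2.54). Lower were LRP1B (111 and 14.9 CPM, 7.45-fold lower, 6.86 to 8.10), the adhesion gene ALCAM (106 and 16.2 CPM, 6.53-fold lower, 6.02 to 7.09) and the calcium-regulated transcription factor NFATC2 (182 and 43.9 CPM, 4.15-fold lower, 3.93 to 4.39). CTNNA3 (209 and 39.1 CPM, 5.35-fold lower, 5.06 to 5.65) and SNTG1 (189 and 46.6 CPM, 4.05-fold lower, 3.83 to 4.27) turned at the higher resolution, to log2 ratios of 0.045 and 0.47.

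Endothelial-like cells differed between the libraries in single genes and in the clusters they came from. SPARCL1 stood at 57.6 and 509 CPM, 8.84-fold higher, 8.28 to 9.43. The drug efflux pump gene ABCB1 stood at 23.3 and 176 CPM, 7.56-fold higher, 6.81 to 8.40 and IGFBP7 at 474 and 3129 CPM, 6.61-fold higher, 6.45 to 6.76. PLVAP, of the fenestrated endothelium, stood at 838 and 154 CPM, 5.43-fold lower, 5.10 to 5.78. The growth factor IGF2 stood at 7499 and 1632 CPM, 4.6-fold lower, 4.51 to 4.69 and IGFBP5 at 189 and 7.92 CPM, 23.8-fold lower, 18.2 to 31.8. FLT1, a receptor of VEGF, stood at 824 and 433 CPM, 1.90-fold lower, 1.83 to 1.98, EMCN at 601 and 433 CPM, 1.39-fold lower, 1.33 to 1.45 and EGFL7 at 569 and 570 CPM, ratio 1.00, 0.966 to 1.04. At 4 weeks the class held cells of clusters 9, 18, 20, 26 and 30 (306, 507, 430, 220 and 55 cells), and at 8 weeks mainly clusters 9 and 30 (534 and 89 cells). Within those shared clusters, an alternative chosen after seeing the data, the log2 ratio of SPARCL1 was 1.48 in place of 3.14. ABCB1 stood at 1.30 in place of 2.92, and IGFBP7 at 1.35 in place of 2.72. PLVAP stood at −0.88 in place of −2.44, IGF2 at −0.77 in place of −2.20 and IGFBP5 at −2.72 in place of −4.56.

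The matrix list had a median log2 ratio of 1.35 (0.83 to 2.0, percentile 100) in endothelial-like cells with 39 of 41 members higher, and 0.55 in the shared clusters. HOX genes had a median of −1.77 (−2.65 to −0.20, percentile 0) with 22 of 30 lower, such as HOXB7 (38.7 and 2.49 CPM, 15.5-fold lower, 9.64 to 26.8) and HOXA9 (25.3 and 3.96 CPM, 6.38-fold lower, 4.33 to 9.76), and −1.04 in the shared clusters. Notch genes had a median of 0.55 (0.37 to 0.77, percentile 99.9) with 13 of 16 higher, such as NOTCH3 (11.8 and 50.032 CPM, 4.25-fold higher, 3.61 to 5.02), but −0.081 in the shared clusters. Over all kept cells of the 8-week library NOTCH3 stood at 91.5 CPM, above its endothelial-like level. Whether free RNA enters the endothelial-like value of NOTCH3 was not tested. Antigen presentation and interferon genes had a median of 0.46 (−0.025 to 1.36, percentile 99.04) over 16 members, and 1.15 in the shared clusters. The interferon-induced ISG15 stood at 19.6 and 143 CPM, 7.31-fold higher, 6.52 to 8.20. CD74, the class II invariant chain, stood at 441 and 93.8 CPM, 4.71-fold lower, 4.34 to 5.11, a log2 ratio that shrank from −2.23 to −0.40 in the shared clusters. The G2 and M phase list had a median of −0.29 (−0.56 to −0.076, percentile 0.240), but 0.042 in the shared clusters.

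Macrophage-like cells had slightly higher levels of the complement genes C1QA (2743 and 3084 CPM, 1.12-fold higher, 1.08 to 1.17) and C1QB (2377 and 2898 CPM, 1.22-fold higher, 1.17 to 1.28), which mark tissue macrophages. The chemokine CCL4 stood at 3379 and 10214 CPM, 3.02-fold higher, 2.92 to 3.13 and MS4A6A at 397 and 922 CPM, 2.32-fold higher, 2.09 to 2.58. The neutrophil-attracting chemokine CXCL8 stood at 256 and 19.1 CPM, 13.4-fold lower, 10.6 to 17.0. The progenitor transcription factor MYB stood at 150 and 21.4 CPM, 7.01-fold lower, 5.45 to 9.02 and GPNMB at 139 and 20.9 CPM, 6.67-fold lower, 5.15 to 8.63. The G2 and M phase list had a median log2 ratio of −0.53 (−0.75 to −0.25, percentile 0) with 25 of 33 members lower. Antigen presentation and interferon genes had a median of −0.22 (−0.69 to 0.32, percentile 18.0), which turned to 0.51 with thinned cells, where B2M stood at 2144 and 4185 CPM and CD74 at 1081 and 687 CPM. The matrix list had a median of 2.02 (1.47 to 2.48, percentile 100) with 38 of 40 higher, and 0.93 with the highest doublet scores removed, which also moved the median of all genes by −0.20. DCN and COL3A1, which are stroma genes named here after their values were seen, stood at 28.1 and 424 CPM and 24.8 and 308 CPM. The macrophage-like class had 141 cells at 4 weeks and 886 at 8 weeks.

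Smooth-muscle-like cells, from cluster 16 in both libraries, had more of some contractile genes, ACTA2 (1175 and 3284 CPM, 2.80-fold higher, 2.64 to 2.96), TAGLN (903 and 2188 CPM, 2.42-fold higher, 2.27 to 2.59) and CNN1 (28.1 and 111 CPM, 3.96-fold higher, 2.74 to 5.93) at 8 weeks. The markers RGS5 (666 and 616 CPM, ratio 0.926, 0.853 to 1.01) and NOTCH3 (309 and 307 CPM, ratio 0.995, 0.882 to 1.13) kept like levels. The cells also had more of ACTG2 (67.4 and 221 CPM, 3.27-fold higher, 2.58 to 4.22) and of elastin (ELN, 83.3 and 266 CPM, 3.19-fold higher, 2.57 to 4.01). The transcription factor MECOM stood at 372 and 1.31 CPM, 284-fold lower, 129 to 778, GALNTL6 at 475 and 12 CPM, 39.6-fold lower, 29.9 to 53.2 and the integrin ITGA8 at 242 and 41.7 CPM, 5.82-fold lower, 4.81 to 7.05. The S phase list had a median log2 ratio of 0.43 (0.045 to 0.86, percentile 99.92) with 22 of 29 members higher, and glycolysis and hypoxia genes 0.37 (−0.19 to 0.51, percentile 99.5) with 17 of 26 higher. HOX genes had a median of −0.66 (−1.38 to 0.078, percentile 0.25) over 21 members, and −0.040 over those with at least 50 UMIs. Genes of early embryonic timing had a median of −0.87 (−1.17 to −0.086, percentile 0) with 12 of 15 lower.

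Erythroid-like cells, 500 at 4 weeks and 62 at 8 weeks, differed in part of their haemoglobins. The embryonic beta-type globin HBE1 stood at 2505 and 416 CPM, 6.02-fold lower, 5.14 to 7.1 and the alpha globin HBA1 at 13121 and 42404 CPM, 3.23-fold higher, 3.17 to 3.29, while AHSP, a chaperone of alpha globin, stood at 6474 and 5692 CPM, 1.14-fold lower, 1.09 to 1.19. The embryonic zeta globin HBZ stood at 1568 and 1721 CPM, 1.10-fold higher, 1.01 to 1.19, a log2 ratio of 0.14 that turned to −0.35 with every cell given the same weight. ARG1, the arginine-cleaving enzyme, stood at 31.9 and 157 CPM, 4.93-fold higher, 3.54 to 6.83. Ribosomal protein genes had a median log2 ratio of −0.34 (−0.48 to −0.25, percentile 46.2) with 38 of 44 lower, beside a median of all genes in this class of −0.49. With every cell given the same weight the log2 ratio of HBE1 was −4.37 in place of −2.59.

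**Figure D4:**
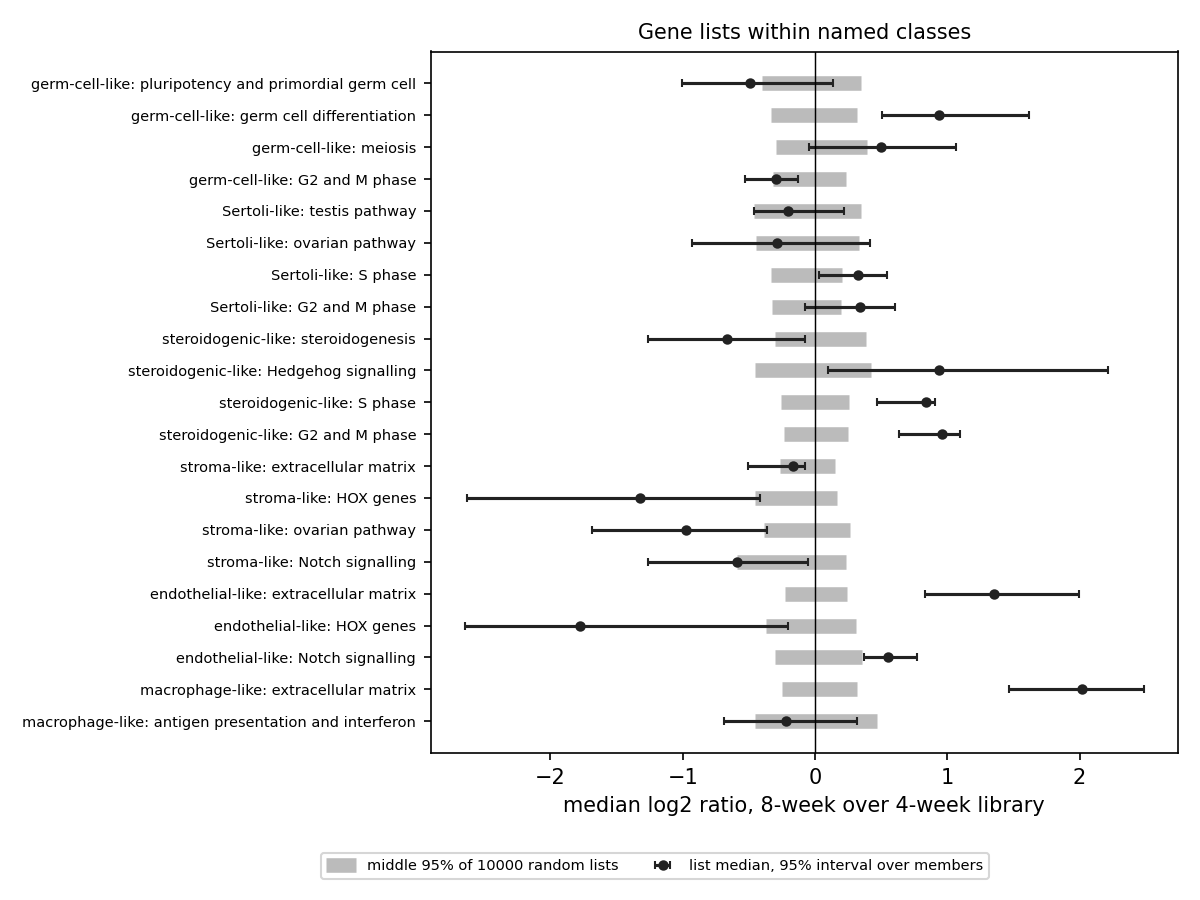
Median log2 ratio, 8 weeks (library labelled ovary) over 4 weeks, of 21 pairs of gene list and cell class, with its 95% interval over the members as a line and the middle 95% of 10000 random lists of like expression as a grey bar. The germ cell differentiation list stood at 0.94, the steroidogenesis list in steroidogenic-like cells at −0.66 and the HOX list in stroma-like cells at −1.33.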

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

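The tests of explanations in this part were chosen after the results they bear on had been seen. SRY had 427 UMIs in the 4-week library and 1494 in the 8-week library labelled ovary, above the limit of 3 that a count of 0 allows. SRY belonged to a sex check fixed before the data were examined, for which no comparison was made, and to the testis list. Of the 11 genes of that check it was the only 1 found among the features by symbol, so the sex-linked evidence rests on 1 gene. The genes of the testis pathway around it were examined as a pattern.

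Testis genes in the library labelled ovary may stem from an XY fetus, which stays a hypothesis because it was found and tested on the same data. UMIs carried over from the 4-week library would leave fewer there, yet SRY, AMH, INSL3 and CYP17A1 each had more in total at 8 weeks, by 3.50, 1.55, 47.1 and 1.98 times, which argues against that source with a lowest ratio of 1.553. Reads of the related SOX3 counted as SRY would put SRY in germ-cell-like cells, where its level was 0.155 of that in Sertoli-like cells (0.0878 to 0.256), which argues against it. At 8 weeks the SRY level over Sertoli-like, stroma-like and steroidogenic-like cells was 4.99 times (3.77 to 6.75) that over germ-cell-like, endothelial-like and macrophage-like cells. These groups held 955 against 51 UMIs, and the ratio was 20.5 (11.8 to 39.0) at 4 weeks. A gonadal somatic source of SRY predicts this. The stroma-like class takes in gonadal and mesonephric stroma, however, so the ratio does not show that the source is gonadal. The rest of the 8-week SRY UMIs lay in cells outside these classes. Free RNA spread over all cells would give each thinned cell of the 8-week library about the same chance of a UMI, with a variance near the mean. Over 13171 cells of any class the variance of UMIs per cell was 6.78 times the mean for AMH, 7.70 for INSL3 and 14.3 for CYP17A1, which argues against free RNA as the source of these genes, while SRY, at 0.0104 UMIs per thinned cell, was too sparse for this test. A wrong tissue label, a mix of fetuses of both sexes and an XY fetus recorded as female were not separated, and the 8-week change in each gene also carries the difference in stage and dissection.

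Matrix genes were higher at 8 weeks in macrophage-like cells, with a median log2 ratio above that of stroma-like cells by 2.18. In stroma-like cells the list (−0.16, percentile 21.2) lay within random lists of like expression and so was not set apart from other genes. The median was also positive in germ-cell-like, Sertoli-like and steroidogenic-like cells (0.82, 1.38 and 1.18). Free RNA would put the genes at 1 share of their all-cell level. An earlier test used only genes picked for low levels in these classes, a choice that itself limits the shares, and is set aside. Over the 40 measured members, the share in macrophage-like cells had quartiles of 29.5% and 35.2%, a ratio of 1.19. The exception was MFAP5 at 1447%, and the other 39 members lay between 23.8% and 40.8%. Free RNA of stroma would give such a near-constant share, but doublets with stroma cells would give it too. The ratio therefore does not favour free RNA over doublets. Whether matrix UMIs were spread evenly over the macrophage-like cells was not tested. In endothelial-like cells the quartiles were 33.7% and 254%, a ratio of 7.55, which argues against free RNA as the whole source there. Free RNA was not tested in the other classes. Genes of other sources had other shares, with AMH at 42.7% in macrophage-like and 17.3% in endothelial-like cells, and NR0B1 at 35.0% and 28.2%. POU5F1 lay at 21.7% and 17.9%, CYP17A1 at 12.8% and 8.49% and INSL3 at 11.2% and 5.69%, so 1 share for all free RNA does not hold. Doublets with stroma cells cannot be told apart from free RNA in macrophage-like cells. After thinning, 17.3% (14.8 to 20.04) of the 8-week macrophage-like cells held a DCN UMI, close to the limit of 20% set for the test. The holders had a median of 1 UMI. To call doublets, the test asked for more DCN UMIs per thinned holder than stroma-like cells themselves carry at 2103 CPM. Doublets could not have met that condition, so the test decides nothing. With the top doublet scores removed, an alternative added after seeing the data, the macrophage-like matrix median was 0.93 in place of 2.02, which goes with doublets as part of the source. That removal also formed new clusters, and cells with more free RNA of stroma could score high too, so the explanation stays open. In steroidogenic-like cells the same removal gave 1.77 in place of 1.18.

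Several list medians had opposite signs in different classes, and the difference between the classes was not tested in any of them. In erythroid-like cells the median of all genes was −0.49, and there the G2 and M phase list (−0.55, percentile 19.6) and the ribosomal protein list (percentile 46.2) lay within random lists of like expression. The G2 and M phase list had a median log2 ratio higher by 1.51 in steroidogenic-like than in erythroid-like cells, where the 8-week class had 62 cells. The steroidogenesis list differed by 1.07 between endothelial-like cells (0.41), a class that should lack these genes and shows the level of free RNA, and steroidogenic-like cells (−0.66). Notch genes differed by 1.14 between endothelial-like and stroma-like cells, and the endothelial-like median turned to −0.081 in the clusters that both libraries shared. Stress genes differed by 0.88 between germ-cell-like and stroma-like cells, and the germ-cell-like median turned to −0.0026 without the rule on high-UMI clusters. Ribosomal protein genes differed by 0.71 between smooth-muscle-like cells (0.37) and erythroid-like cells (−0.34).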

How the results depend on the processing

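No paired analysis was possible because each group was 1 library, and no result comes from a test. Of the list medians in the text, 61 were taken under alternatives, which gave 657 values. Of these 657 values, 622 stayed within the interval of the reported value, 31 moved out of it and 4 reversed, that is, took the other sign where the reported interval excluded 0. In all, 20 of the 657 had the other sign. Of 1850 values of 370 gene log2 ratios, 1399 stayed, 431 moved and 20 reversed, and 44 had the other sign. Part of the list and gene values that stayed could not move. Naming without the rule on high UMIs changed only germ-cell-like cells. The shared clusters were the whole class for germ-cell-like, steroidogenic-like, smooth-muscle-like and erythroid-like cells. Of 145 class shares 102 stayed. The 145 leave out each share whose class had no cells or no name under an alternative, so total losses are not counted. Among those left out is the stroma-like share of the library labelled ovary with each library clustered alone. The mesonephric-tubule-like, podocyte-like and lymphoid-like shares at the lower resolution were also left out. Of 288 shares of cells with a UMI 73 stayed without thinning. The causes were not tested. The germ cell differentiation median ranged from 0.92 to 1.19 and the steroidogenesis median from −0.76 to −0.62.

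Shares at 4 and 8 weeks were, for germ-cell-like cells, 6.49% and 8.79% at resolution 0.5 and 7.37% and 8.73% without the rule on high UMIs. Sertoli-like shares were 8.68% and 7.61% with at least 1000 genes, 9.41% and 7.86% at resolution 0.5, 6.14% and 7.58%, the other way round, with each library alone, and 8.08% and 6.84% without the top doublet scores. The 8-week Sertoli-like share was 4.61% at resolution 2.0, and the 8-week steroidogenic-like share 4.48% with at least 1000 genes.

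In shared clusters only, an alternative added after seeing the data like the naming rule and the doublet scores, median log2 ratios became −0.21 (S phase, Sertoli-like), −0.081 (Notch, endothelial-like) and 0.042 (G2 and M phase, endothelial-like). There ALDH1A2 became −0.034 and INHBB 0.55 in Sertoli-like and HOXD9 −0.28 in endothelial-like cells. The germ cell stress median became −0.0026 without the naming rule.

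At resolution 2.0 the stroma-like medians were −0.65 for matrix and −3.04 for HOX genes. There CTNNA3 became 0.045, SNTG1 0.47, ID1 −0.15, ID3 −0.33 and IER3 −0.12, and in Sertoli-like cells TGFB2 became −0.27 and WNT4 −0.67. With every cell the same weight, the stroma-like matrix median was −0.060 (−0.068 thinned), ZNRF3 0.0019, ID1 −0.16, ID3 −0.013, HOXD4 0.21, IER3 −0.18 and HSPB1 −0.063. In the same setting TDRD9 was 0.062 in germ-cell-like, DLK1 −0.13 in smooth-muscle-like and HBZ −0.35 in erythroid-like cells. COL1A2 was 0.016 in stroma-like cells without ribosomal protein and haemoglobin genes.

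Settings moved the median log2 ratio of all genes by −0.12 in Sertoli-like cells (resolution 2.0), 0.12 in endothelial-like cells (thinned) and 0.29, 0.25 and 0.13 in erythroid-like cells (top doublet scores, libraries alone, thinned). Stroma lists have no value with each library alone, since no 8-week cells were named stroma, and lists were not run at resolution 0.5. At that resolution no cluster was named mesonephric tubule, podocyte or lymphoid. Depth limits the classes with few cells, such as 62 erythroid-like cells at 8 weeks and 123 smooth-muscle-like cells at 4 weeks.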

Other observations

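Most tests in this part were chosen after the results they bear on were seen, and the test in cluster 28 was set before its value was seen. Some cells outside the named classes had clear leading genes, which are given here as values chosen after they were seen. Clusters 14 and 24 held 592 and 287 cells of the 4-week library, 6.64% (6.14 to 7.18) and 3.22% (2.86 to 3.61), and none of the library labelled ovary. Both met 13 of the markers of the mesonephric tubule, 68.4% of those measured, but also 55.6% of those of hepatocytes, and so stayed unnamed. Cluster 24 was led by AFP, GPX3, FGB, TINAG and CUBN, and cluster 14 by APOC2, FBP1, PVALB and TTR. The 10.2% of mesonephric-tubule-like cells in the 4-week library therefore leaves out cells that carry many of the same markers. Cluster 19, with 434 cells of the 4-week library (4.87%, 4.43 to 5.34), was led by EYA1, EYA4, GDNF and ROBO2, genes of kidney progenitors.

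In the library labelled ovary, cluster 1 held 1976 cells (13.5%, 13.0 to 14.1) against 398 at 4 weeks (4.47%, 4.05 to 4.92). Its leading genes included RXFP2, the receptor of INSL3, and the opioid precursor PENK, and it met markers of stroma and of surface epithelium at close shares of 38.9% and 33.3%. Cluster 32, with 38 and 63 cells, was led by the neutrophil and monocyte genes S100A12, S100A9, S100A8 and LYZ. FOXL2, a granulosa gene, had its highest level among the 8 compared classes in steroidogenic-like cells, at 17.6 CPM (13.8 to 22.2) and 8.31 CPM (6.85 to 9.99).

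IDO1, an enzyme that breaks down tryptophan, was the feature with rank 1 by UMIs in the 4-week library and rank 4 at 8 weeks, with 1.59% and 0.542% of all UMIs, and took 19.97% of the UMIs of distal-tubule-like cells and 19.6% in the unnamed cluster 28 at 8 weeks. It took 5.56% and 6.61% in the 4-week clusters 14 and 24. A second feature, LOC123281922, had 1.38% of the 4-week UMIs, with 12.9% in distal-tubule-like cells, 4.64% and 5.90% in clusters 14 and 24, and 4.85% in cluster 28 at 8 weeks. An interferon response may raise IDO1, but antigen presentation and interferon genes had a median log2 ratio of −1.02 (−1.75 to 0.24, 16 members) in distal-tubule-like over other 4-week cells, an interval that decides nothing. Mitochondrial transcripts counted at this nuclear feature are a candidate source: nuclear-encoded oxidative phosphorylation genes, a list written after the first look, stood at 1.14 (0.91 to 1.47, 37 members) there, but tubule cells are rich in mitochondria in any case. In cluster 28 the same list stood at −1.06 (−1.30 to −0.99), the outcome set beforehand for a source other than mitochondrial transcripts. This value does not decide the source there, since damage to these cells could also lower nuclear-encoded genes. The median of all genes was 0.96, but it is no baseline for this list. The 0.5 UMI added to each sum raises sparse genes in a cluster with so few UMIs. Barcodes of cluster 28 had a median of only 669 UMIs, and damage to these cells was not tested. Whether the IDO1 feature counts IDO1 messenger RNA cannot be settled without the sequence, and no biological explanation was tested beyond the interferon genes.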
